A study of Mus musculus with 4 samples.

How the data were processed

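RNA was measured in 4 libraries of G1ER cells, a mouse erythroblast line that lacks its own GATA1 and matures when beta-estradiol activates an introduced fusion of GATA1 with the estrogen receptor. Wild-type cells and a Chd7 knockout line were each sampled at 0 h and after 24 h of estradiol, with 1 library per group. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a random-primed kit. Genotype and time were taken from the sample titles, because the treatment label reads estradiol for all 4 libraries, including those titled 0 h.

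The authors deposited FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), 1 value per gene symbol and library. The submitters' processing notes name FastQC, cutadapt, TopHat2 2.0.11 and Cufflinks 2.2.1 with the mouse genome build GRCm38. The gene annotation, the treatment of reads that map to several places and the scaling between libraries are not given in the sources used here. The table held 23936 gene rows, of which 10411 were listed at 0 in all 4 libraries. Each of its 4 value columns was mapped to a library by the name in that library's description. For the knockout at 24 h the column name is longer than the description by a suffix and starts like no other description.

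FPKM holds no total count, so depth was approximated from the low values. For genes with a single annotated transcript of at least 3 kb, the FPKM step worth 1 fragment was sought in each library. The steps gave about 15.03 M and 17.9 M fragments for wild type at 0 and 24 h, and 14.8 M and 15.9 M for the knockout (M, mega). Between 54.7% and 56.5% of the low values used were whole fragments within 5%, so these depths are approximate and no count test was run. The tolerance widens with the number of fragments, and no baseline share was taken. As the scaling between libraries is not given, the steps can reflect a rescaled total instead of the fragments in a library. At the lowest of these depths, 1 FPKM on a 2-kb transcript was about 29.5 fragments. The 95% half-width from counting alone was then 0.74 for a log2 ratio of FPKM with nothing added. At 5 FPKM it was 0.33 and at 50 FPKM 0.10. For ratios of FPKM + 1, used below, the half-width is smaller, most so at low values. These intervals cover counting error only.

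Values were compared as log2(FPKM + 1), which understates the change of low genes, for the 8964 genes with a mean of at least 1 FPKM over the 4 libraries. There were 5 comparisons, namely 24 h against 0 h in each genotype, knockout against wild type at each time, and the difference of the estradiol responses (knockout minus wild type). A gene was counted as higher or lower when its ratio reached 2-fold, a log2 ratio of 1, and for the difference of responses when the difference of log2 ratios reached 1. With 1 library per group there was no replicate check, so no p-value was computed, and each statement is about these libraries.

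Gene lists (34) were fixed before the data were examined, and 30 had at least 3 measured members. A list's relative median is the median log2 ratio of its members minus the median of all genes. Its percentile was taken among 10000 random lists of equal size, matched on mean expression in 20 bins, and a list stands apart at a percentile of at most 1 or at least 99. This rule takes about 0.60 of 30 lists by itself. The percentile describes these libraries and is not a test of the conditions.

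Genes are named by rules that were also fixed before the data were examined. They are a set of anchor genes, and per comparison the 8 genes most higher and the 8 most lower among those with at least 5 FPKM in the higher library, small RNA and predicted loci left out. Added to them are up to 3 members most higher and 3 most lower of each list described, and up to 10 genes per direction that differed at least 2-fold between genotypes at both times. A few genes were chosen after their values were seen, and the text says so. 1 result that falls under these rules is not reported.

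Gene positions were taken from the RefSeq annotation of GRCm38, which matched 8407 of the 8964 genes (93.8%) by symbol. Chromosomes were compared over the 8030 of these that lie on chromosomes 1 to 19 or X and are no small or predicted loci, while the setting without chromosome 5 leaves out its small and predicted loci too. The chromosome comparison, the counts without chromosome 5, the counts limited to ratios beyond the counting interval, and the share of responding genes with the larger response in the knockout were added after the data were seen. All other settings were planned, namely pseudocounts of 0.1 and 5 FPKM, no filter, a mean of at least 5 FPKM, scaling to an equal sum per library (transcripts per M, TPM), median-centred libraries, upper-quartile scaling, small and predicted loci left out, and random lists not matched on expression.

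The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated libraries of the 8964 genes at these depths, in which 200 genes were changed 3-fold and a spread of 10% beyond counting was assumed. The 2-fold rule found 88.0% of them for the wild-type response, 93.0% for the knockout response, 90.5% and 85.5% for knockout against wild type at 0 and 24 h, and 85.5% for the difference of responses. It took 0 of 8744 unchanged genes in each of the single comparisons and 9 in the difference. Of 100 unshifted lists, between 1 and 3 per comparison stood apart. Each gene was simulated as a 2-kb transcript, so these figures do not cover shorter loci such as small RNAs, which have fewer fragments per FPKM. The true spread between cultures is unknown and can be larger than the one assumed.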

Results

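The study asked how loss of CHD7, a chromodomain helicase that remodels nucleosomes, affects the erythroid maturation of G1ER cells. Expression was measured in wild-type and Chd7 knockout cells at 0 h and at 24 h of beta-estradiol, with 1 library in each of the 4 groups and therefore no replicates. Approximate depths from the low FPKM values were 15.03 M and 17.9 M fragments in wild type at 0 and 24 h. In the knockout they were 14.8 M and 15.9 M. They are totals behind the FPKM scaling, which need not equal the fragments in each library. Summed FPKM was 923195 and 780536 in wild type at 0 and 24 h and 1604981 and 753591 in the knockout. Small RNA and predicted loci held 33.2%, 17.3%, 63.2% and 20.97% of these sums in the same order, and the snoRNA gene Snord49a alone held 33.9% of the sum of the knockout at 0 h. The log2 values of the libraries correlated across genes with Pearson's r of 0.96 between genotypes at each time.

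Chd7 (chromosome 4, 8690402 to 8868449, GRCm38) was listed at 0 FPKM in all 4 libraries, wild type included. Hmgcs1, Insig1, Phgdh, Ube2d1 and Zfp131, genes that most cells use and that were picked after their values were seen, were also listed at 0 in all 4 libraries. A listed 0 in this table therefore need not be a measured absence, and the Chd7 row could not check the knockout labels. Of the other chromodomain helicases, 8 were measured, and none of them differed 2-fold between genotypes. Chd4, the most abundant, stood at 122 FPKM in wild type and 108 in the knockout at 0 h, and at 83.9 and 59.0 at 24 h. Runx1, a blood transcription factor that the title of the series names beside CHD7, was at 5.76 and 6.32 FPKM in wild type and 5.24 and 7.24 in the knockout at 0 and 24 h.

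Estradiol in wild-type cells was followed by high expression of the red cell program. Of the globin list, 6 of 6 measured members were at least 2-fold higher at 24 h. Hbb-b1, an adult beta-globin gene, went from 326 to 7865 FPKM (log2 ratio 4.59) and Hba-a1, an adult alpha-globin gene, from 114 to 1594 (3.79). Alas2, the erythroid enzyme that opens heme synthesis, went from 2.32 to 58.3 FPKM, and Slc4a1, the anion exchanger of the red cell membrane, from 0.10 to 20.6. Lower at 24 h were Gata2, a transcription factor of progenitors (21.9 to 5.53 FPKM, log2 ratio -1.81), Kit, the stem cell factor receptor (39.4 to 20.4, -0.92), and Cpa3, a mast cell protease (11.2 to 1.16, -2.49).

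By list, heme synthesis had 7 of 13 members at least 2-fold higher and 0 lower in wild type, among them Abcb10 (24.8 to 128 FPKM) and Alad (17.4 to 66.0), with a relative median of 1.26. Red cell membrane and skeleton genes had 11 of 18 higher, with a relative median of 1.49, for example Ank1 (ankyrin, 4.93 to 21.9 FPKM). Sptb, the beta-spectrin gene, chosen after its values were seen, went from 33.2 to 132. Erythroid regulators had 0 of 15 members beyond 2-fold but a relative median of 0.39 (percentile 99.99), with Klf1 at 54.0 and 99.2 FPKM and Lmo2 at 33.2 and 61.0. Iron handling genes (0.49), CDK inhibitors and other anti-proliferative genes (0.44), autophagy genes (0.48), replication-dependent histones (0.37), glycolysis genes (0.37), known RUNX1 targets (1.01, 7 of 21 listed genes measured) and p53 targets (0.22) also stood apart on the higher side. Ccng2 (12.6 to 29.2 FPKM) and Btg2 (0.31 to 3.19), both anti-proliferative, were at least 2-fold higher, and Tfrc, the transferrin receptor, stood at 269.9 and 386.

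Standing apart on the lower side in wild type were progenitor genes that are known to go down when GATA1 is restored (relative median -0.71), mast cell and basophil markers (-1.91, 5 of 16 listed genes measured), ribosome biogenesis factors (-0.43), amino acid stress genes (-0.19) and abundant non-coding RNAs (-0.15). Of the 10 progenitor genes 3 were at least 2-fold lower, and Spi1, which encodes PU.1, went the other way (12.9 to 25.02 FPKM). Ms4a2 and Il1rl1, markers of mast cells, went from 8.01 to 1.14 and from 17.2 to 3.47 FPKM. The amino acid stress list did not stand apart without chromosome 5 (percentile 12.9), iron handling not at a mean of at least 5 FPKM (percentile 98.98), and the non-coding RNAs not without small and predicted loci (percentile 2.19). The amino acid stress call was also lost with no filter (percentile 2.54) and at a mean of at least 5 FPKM (15.79). The non-coding call was also lost with no filter (3.06), at that mean (1.175) and among unmatched lists (9.835). With no filter, which adds genes near 0, the relative medians were 2.33 for globins, 0.20 for RUNX1 targets, 0.13 for p53 targets and -0.16 for mast cell markers, and with a pseudocount of 5 FPKM they were -1.01 for mast cell markers, 0.21 for anti-proliferative genes and 0.14 for p53 targets, all still standing apart. Of all 8964 genes, 167 were at least 2-fold higher and 95 lower (63.7% higher among them), against 201 and 65 with median-centred libraries (75.6%) and 269 and 49 with TPM scaling (84.6%). The median log2 ratio of all genes was -0.11.

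**Figure D1:**
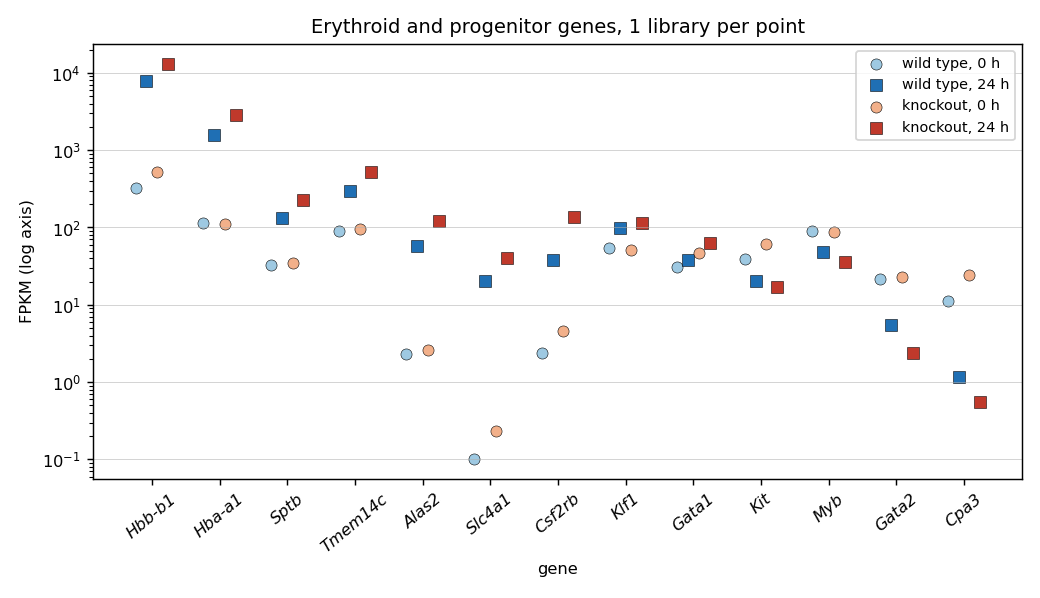
FPKM (log axis) of 13 erythroid and progenitor genes, 1 point per library, with circles for 0 h and squares for 24 h of estradiol and blue for wild type and orange to red for the knockout. Hbb-b1 stood at 7865 FPKM in wild type and 13127 in the knockout at 24 h, and Gata2 at 5.53 and 2.40.

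In the knockout line globin, heme synthesis and red cell membrane genes were higher at 24 h than at 0 h, and progenitor and mast cell genes lower. Hbb-b1 went from 528 to 13127 FPKM (log2 ratio 4.63), Alas2 from 2.62 to 123 (5.10) and Slc4a1 from 0.24 to 40.7 (5.08). Gata2 went from 23.0 to 2.40 FPKM (log2 ratio -2.82), Kit from 61.3 to 17.1 (-1.78), Myb from 87.6 to 35.3 (-1.29) and Cpa3 from 24.6 to 0.56 (-4.03). Csf2rb and Csf2rb2, which encode beta chains of cytokine receptors, went from 4.63 to 138 and from 0.79 to 38.7 FPKM.

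Heme synthesis genes had 10 of 13 members at least 2-fold higher in the knockout (relative median 1.90), with Tmem14c at 95.9 and 527 FPKM and Slc25a37, the mitochondrial iron importer, at 4.19 and 29.1. Red cell membrane genes had 14 of 18 higher (1.91), globins 6 of 6 (3.57), and erythroid regulators 4 of 15 (0.56), among them Zfpm1, the GATA1 cofactor FOG1 (39.9 to 101 FPKM). Progenitor genes had 7 of 10 lower (-1.29), including Lyl1 (65.4 to 21.7 FPKM) and Vim (7.76 to 0.87), and ribosome biogenesis factors 6 of 25 lower (-0.64), including Heatr1 (46.9 to 19.1 FPKM) and Polr1b (32.4 to 13.6). Mast cell markers, of which 5 of 16 were measured, had a relative median of -2.95, against -1.85 with a pseudocount of 5 FPKM and -0.19 with no filter. Autophagy genes (0.68), anti-proliferative genes (0.66), RUNX1 targets (0.59), histones (0.33), mitotic genes (0.30), cholesterol synthesis (0.27) and glycolysis (0.26) stood apart as higher, cholesterol synthesis not without chromosome 5 (percentile 98.6). The cholesterol call was also lost with a pseudocount of 0.1 FPKM, with no filter (percentile 98.9 each) and among unmatched lists (98.95). Iron handling did not stand apart (0.14, percentile 89.0), though it did without chromosome 5 (0.49, percentile 99.96). The p53 targets (percentile 83.4), amino acid stress genes (4.19) and abundant non-coding RNAs (53.5), which stood apart in wild type, did not in the knockout. The difference of responses did not stand apart for p53 targets (-0.07, percentile 13.02) or amino acid stress (-0.02, percentile 67.9), so these are not shown to differ between genotypes. With no filter the values were 2.21 for globins, 0.105 for RUNX1 targets and 0.15 for glycolysis, with a pseudocount of 5 FPKM 0.38 for anti-proliferative genes, and at a mean of at least 5 FPKM 1.02 for RUNX1 targets. Glycolysis did not stand apart at a mean of at least 5 FPKM (percentile 98.7). Of all genes 303 were at least 2-fold higher and 326 lower (48.2% higher), against 384 and 235 with median-centred libraries (62.0%), 376 and 250 with upper-quartile scaling (60.1%) and 3043 and 39 with TPM scaling (98.7%). The all-gene median was -0.12.

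The responses of the genotypes, which share no library, were compared gene by gene. Both genotypes had 139 genes in common among the higher ones, where independent lists would share 5.64, and 69 among the lower ones, where 3.45 would be shared. Opposite directions were found for 5 genes (6.07 by independent lists) and 4 genes (3.21). Across the 8964 genes, which are not independent replicates, Pearson's r was 0.55 and Spearman's rho 0.78, and r was 0.82 without small and predicted loci. Through the 674 genes at least 2-fold changed in either genotype, the orthogonal slope of the knockout on the wild-type response was 1.31. Among genes whose mean response over both genotypes was at least 2-fold, the response was larger in the knockout for 196 of the 229 higher genes (85.6%, exact 95% interval 80.4% to 89.9%) and for 158 of the 173 lower genes (91.3%, 86.1% to 95.1%). These intervals treat genes as independent draws, which they are not, and do not cover the spread between cultures. With TPM scaling the share among lower genes was 54.1%.

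**Figure D2:**
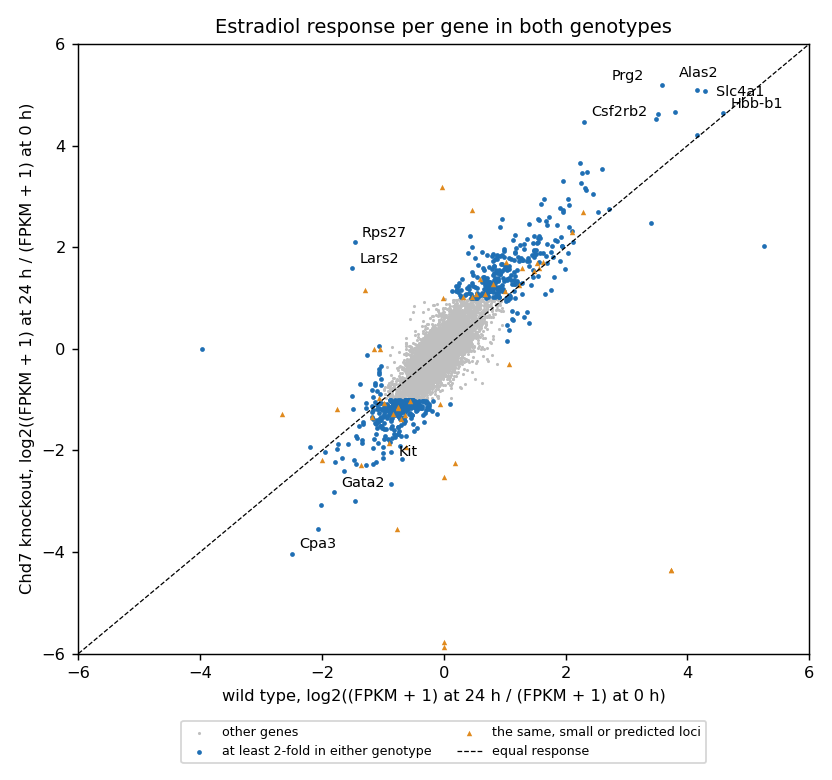
Log2 ratio of (FPKM + 1) at 24 h over 0 h for each gene in wild type (x axis) and in the Chd7 knockout (y axis), with blue points and orange triangles for genes at least 2-fold changed in either genotype and the dashed line for an equal response. Most of the coloured points lie farther from 0 on the y axis than on the x axis, with an orthogonal slope of 1.31, and 22 genes beyond 6 on either axis are not drawn.

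The difference of the responses was a measured quantity of its own, knockout minus wild type. Heme synthesis genes stood apart with a relative median of 0.61, with Slc25a37 (0.97), Alas2 (0.94), Uros (0.93) and Abcb10 (0.85) in front and Cpox (-0.01) at the other end. Red cell membrane genes had a difference above 0 for 18 of 18 members and a relative median of 0.36, led by Dmtn (1.19), Tspan33 (0.79) and Slc4a1 (0.78). Autophagy genes stood apart at 0.30, with Calcoco1 (0.66) and Optn (0.56) highest, and abundant non-coding RNAs, fixed as a sign of RNA quality and depletion, at 0.11 (percentile 99.1). On the lower side stood the progenitor genes (-0.45), for which 0 of 10 members were above 0 and Vim (-1.12), Gata2 (-1.01) and Kit (-0.86) were lowest, mast cell markers (-1.03), myeloid markers (-0.32) and ribosome biogenesis factors (-0.24). Mast cell markers were at -0.53 with a pseudocount of 5 FPKM and -0.20 with no filter, and with TPM scaling ribosome biogenesis was at -0.15 and the non-coding RNAs at 0.20. The myeloid call was lost with no filter (percentile 2.21), with a pseudocount of 0.1 FPKM (1.18) and at a mean of at least 5 FPKM (3.395). The non-coding call was lost with no filter (percentile 98.79) and among unmatched lists (85.0). The globin list did not stand apart in this comparison (0.07, percentile 90.8).

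Single genes with the largest positive differences of response included Csf2rb2 (2.16), Prg2, which encodes a granule protein of eosinophils (0.19 to 13.2 FPKM in wild type, 0.38 to 49.7 in the knockout), Nxpe2 (1.54) and Tbxas1, the thromboxane synthase gene (0.14 to 1.21 FPKM in wild type, 0.36 to 6.93 in the knockout). The most negative ones included Tspan4 (-1.79), Flna, the actin crosslinker filamin A (62.9 to 22.3 FPKM in wild type, 50.03 to 5.39 in the knockout), Cpa3 (-1.54), C2cd4a (-1.48), Ms4a2 (-1.48) and Akr1b3 (-1.29). Amd1 (3.96), Rps27 (3.56), Lars2 (3.09), Hist1h2ap (-3.24) and Hist1h4n (-10.92) were more extreme, and of these Amd1, Rps27, Hist1h2ap and Hist1h4n belong to families of similar copies. Of all genes, 54 had a difference of at least 1 and 56 of at most -1 (49.1% higher), against 1327 and 25 with TPM scaling (98.2%). Small and predicted loci made up 14 and 27 of them.

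Before estradiol, the knockout line differed from wild type in fewer genes, 39 at least 2-fold higher and 58 lower, of which 24 and 12 were small or predicted loci (40.2% higher in all, against 28 and 1111 or 2.46% with TPM scaling). Mast cell and basophil markers were higher in the knockout at 0 h, with a relative median of 0.81 and 5 of 5 measured members (of 16 listed) above 0. It was 0.32 with a pseudocount of 5 FPKM and 0.20 with no filter, which also gave 0.12 for myeloid and 0.08 for red cell membrane genes. Cpa3 stood at 11.2 FPKM in wild type and 24.6 in the knockout, and Ms4a2 at 8.01 and 19.4. The globin list had a relative median of 0.42 with 3 of 6 members above 0, a call that was lost with no filter (percentile 79.4), and of 0.78 at a mean of at least 5 FPKM. Hbb-b1 stood at 326 and 528 FPKM, and the sum of the near-identical Hba-a1 and Hba-a2 was 145 in wild type and 356 in the knockout. Of these, Hba-a1 stood at 114 and 111 and Hba-a2 at 30.9 and 245. TPM scaling moved the median of all genes at 0 h from -0.07 to -0.78, so that single genes less than that much higher in the knockout, such as Hbb-b1 and Gata1, turn lower, while relative medians are taken against this shift. These were 0.68 for globins, 0.60 for RUNX1 targets, 0.12 for iron handling and -0.19 for ribosomal proteins with TPM scaling.

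The p53 target list was also higher at 0 h, with 15 of 17 members above 0, 3 at least 2-fold higher and a relative median of 0.37 (percentile 100). Zmat3 stood at 2.32 FPKM in wild type and 6.78 in the knockout, Trp53inp1 at 1.47 and 4.998, and Eda2r at 0.25 and 2.89. Ccng1, chosen after its values were seen, stood at 56.2 and 94.2. Myeloid markers (relative median 0.47, percentile 99.95, with Cebpe at 2.93 and 6.55 FPKM), RUNX1 targets (0.40, percentile 99.9), cholesterol synthesis (0.19), iron handling (0.19), progenitor genes (0.19) and red cell membrane genes (0.12) also stood apart as higher. The progenitor list holds Kit (39.4 and 61.3 FPKM), which lies on chromosome 5, and without that chromosome it did not stand apart (percentile 98.6). Its call was also lost with no filter (percentile 98.7), at a mean of at least 5 FPKM (95.6) and with TPM scaling (95.8). With no filter (percentile 60.8) and with a pseudocount of 5 FPKM (98.4) the RUNX1 targets did not stand apart. Without chromosome 5 their relative median was 0.225. Nor did the myeloid markers stand apart at a mean of at least 5 FPKM (percentile 95.98; relative median 0.27 with a pseudocount of 5 FPKM), or the red cell membrane genes among unmatched lists (percentile 98.96). Mitotic genes (-0.20, 22 of 24 members not above 0), glycolysis genes (-0.19) and ribosomal proteins (-0.10) stood apart as lower. Ccnb2, cyclin B2, was at 76.4 FPKM in wild type and 22.5 in the knockout, Top2a at 201 and 139, Slc2a1, a glucose transporter, at 43.7 and 32.2, and Pgk1 at 1442 and 1127.

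After 24 h the red cell program was higher in the knockout than in wild type. Few members reached 2-fold, namely 1 of 6 globins, 1 of 18 red cell membrane genes and 2 of 13 heme synthesis genes. The globin list had a relative median of 0.84, with Hbb-b1 at 7865 FPKM in wild type and 13127 in the knockout and the summed alpha-globin genes at 1931 and 4196. Red cell membrane genes had 17 of 18 members above 0 (relative median 0.66), with Sptb at 132 and 227 FPKM and Dmtn at 4.99 and 11.9. Heme synthesis genes had 13 of 13 above 0 (0.51), with Alas2 at 58.3 and 123 FPKM, Slc25a37 at 13.0 and 29.1 and Abcb10 at 128 and 219.5. The Gata1 row stood at 38.2 FPKM in wild type and 63.7 in the knockout at 24 h, and at 31.1 and 46.7 at 0 h. Because the line lacks its own GATA1, this row cannot be read as the level of an intact gene of the cells. How much of it comes from the introduced fusion is not given in the sources used here.

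Erythroid regulators (relative median 0.20, Zfpm1 at 58.8 and 101 FPKM), p53 targets (0.29), autophagy genes (0.28), cholesterol synthesis (0.25, with Mvk, on chromosome 5, at 15.3 and 30.9 FPKM) and iron handling (0.18) also stood apart as higher at 24 h. Histones stood at percentile 99.3 although their relative median was -0.0017, above nearly all matched lists. They did not stand apart at a mean of at least 5 FPKM (percentile 98.4) or among unmatched lists (48.6). Among unmatched lists the erythroid regulators (percentile 98.2) and iron handling (97.04) did not stand apart either. With no filter the globins stood at 0.27 and iron handling at 0.12. Glycolysis genes stood apart as lower (-0.25), with Pgam1 at 401 FPKM in wild type and 259 in the knockout and Slc2a1 at 58.2 and 34.9. The progenitor, mast cell and myeloid lists, higher at 0 h, did not stand apart at 24 h (percentiles 22.9, 4.92 and 82.3). The single genes most higher included Lars2 (9.05 and 130 FPKM), a member of the list fixed as a sign of RNA quality, Csf2rb2 (6.04 and 38.7) and Cldn13 (23.1 and 89.1), the last on chromosome 5, and those most lower included Hist1h4n (1942 FPKM and near 0), Hist1h2ap (37.5 and 3.11), Coro1a (17.6 and 3.57) and Ifitm2 (51.3 and 12.1), the last pair at least 2-fold lower at 0 h too. Of all genes 64 were at least 2-fold higher and 102 lower (38.6% higher), against 82 and 86 with upper-quartile scaling (48.8%).

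**Figure D3:**
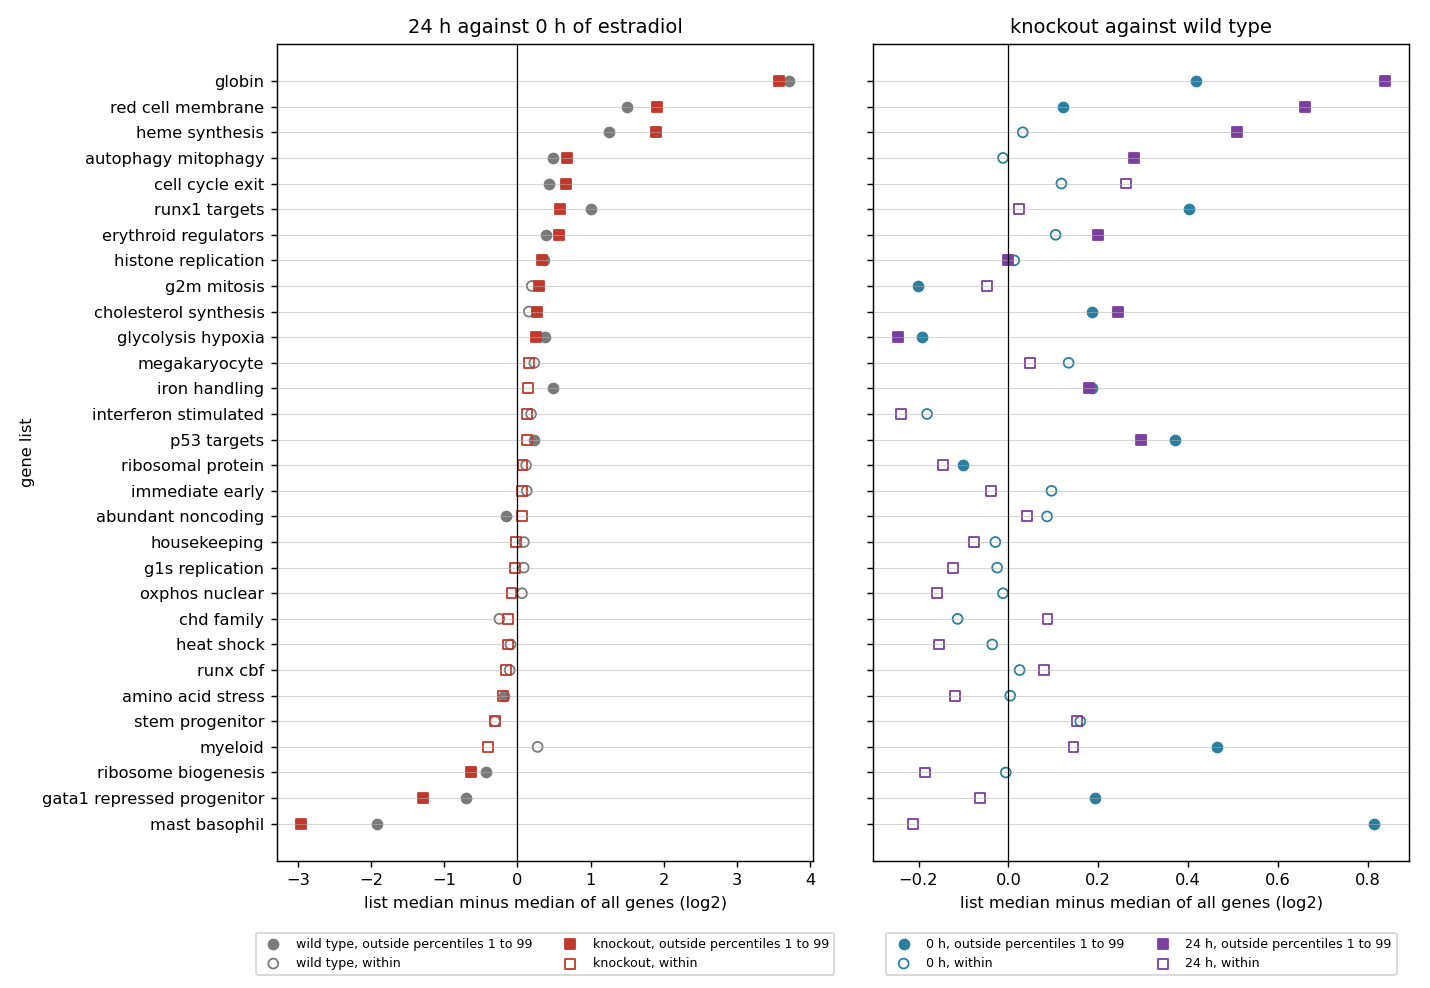
Relative median (list median minus the median of all genes, log2) of the 30 gene lists for 24 h against 0 h of estradiol (left) and knockout against wild type (right), with filled symbols for lists outside percentiles 1 to 99 of matched random lists. Red cell membrane genes stood at 1.49 in wild type and 1.91 in the knockout on the left, and at 0.12 and 0.66 at 0 and 24 h on the right.

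The knockout effects at 0 and 24 h come from separate libraries of the same lines. They correlated across genes with r of 0.35 and rho of 0.45, and r was 0.52 without small and predicted loci. Of the 39 and 64 genes higher at the times 14 were shared (0.28 by independent lists), and of the 58 and 102 lower genes 39 (0.66). Higher at both times were Cd81, a tetraspanin (0.38 and 11.1 FPKM at 0 h, 0.20 and 10.4 at 24 h), Plod2, a lysyl hydroxylase (4.44 and 23.5, 5.09 and 21.7), Cox6b2, Hba-a2, Trp53inp1, Zmat3 and Col18a1. Lower at both times were, among 22 genes under the naming limits, Cyp2c55, a cytochrome P450 (39.1 and 4.42 FPKM at 0 h, 28.5 and 3.001 at 24 h), Ctbp2, a transcriptional corepressor (16.3 and 1.86, 11.7 and 0.88), and Bex4 (102 and 23.5, 81.0 and 11.4). The others named were Bex1, Fkbp11, Ctsl, Slc2a3, Ninl, Mapkapk2 and Ifi27. The mean knockout effect and the mean estradiol effect, which are orthogonal contrasts, correlated across genes with r of 0.13 and rho of 0.30 (r of 0.28 without small and predicted loci).

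Chromosome of origin separated the genes in the knockout comparisons, a feature looked at after the data were seen. With small and predicted loci left out, the 533 genes of chromosome 5 had a median log2 ratio of knockout over wild type of 0.40 at 0 h and 0.34 at 24 h. The medians of the other 19 chromosomes lay between -0.12 and -0.07 at 0 h and between -0.15 and -0.065 at 24 h. None of 10000 random sets of genes of equal size, matched on mean expression, reached the chromosome 5 median of the mean ratio over the times (0.38), the highest being -0.04. Of the 49 such genes with a position that were at least 2-fold higher in the knockout at 24 h, 16 (32.7%) lay on chromosome 5, which holds 6.64% of the genes. At 0 h it was 2 of 14 (14.3%). With small and predicted loci it was 17 of 62 (27.4%) at 24 h and 4 of 38 (10.5%) at 0 h. Kit, Actb, Mvk, Ccng2, Pf4, Add1, Ulk1, Wipi2, Tecpr1, Cldn3, Cldn13 and Tmem184a are on this chromosome, so their ratios between genotypes include this shift.

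**Figure D4:**
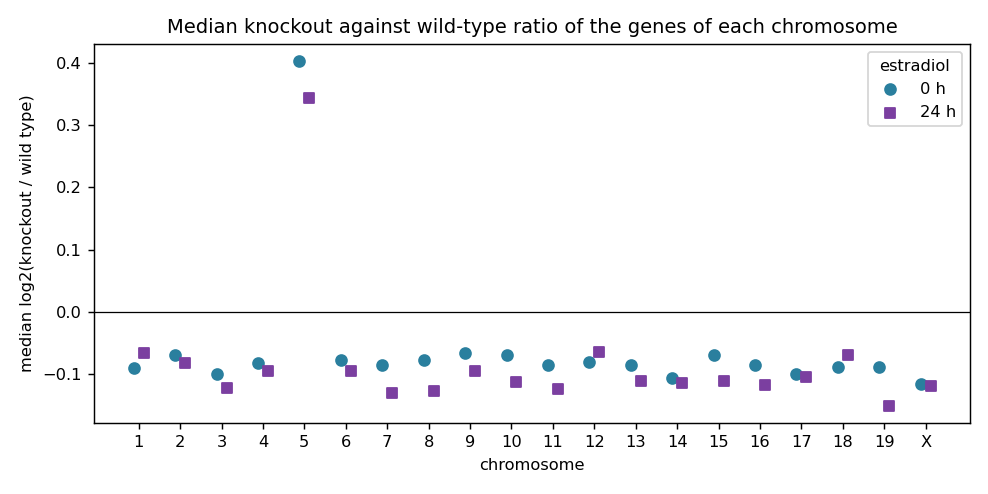
Median log2 ratio of knockout over wild type of the genes of each chromosome, small and predicted loci left out, at 0 h (circles) and 24 h (squares) of estradiol. Chromosome 5 stands at 0.40 and 0.34, and each of the other 19 chromosomes lies below 0.

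Lists without a call in any of the 5 comparisons were megakaryocyte markers, stem cell markers, the RUNX and core-binding factor family, chromodomain helicases, replication genes, interferon-stimulated genes, immediate early genes, heat shock genes, nuclear respiratory chain genes and reference genes. Their relative medians for the knockout against wild type at 24 h lay at 0.05, 0.15, 0.08, 0.09, -0.12, -0.24, -0.04, -0.15, -0.16 and -0.08 in that order. Some gained a call in other settings. With no filter these were megakaryocyte markers and chromodomain helicases (wild-type response, percentiles 99.92 and 0.56), stem cell markers (0 h, 99.2) and immediate early genes (difference, 0.53). Megakaryocyte markers also did without chromosome 5 (wild-type response, 99.14) and with TPM scaling (0 h, 99.92). Respiratory chain genes did among unmatched lists (24 h, 0.875). Lymphoid markers had 0 measured members, and endothelial and fibroblast markers had 1, Egfl7 (37.9 and 23.9 FPKM at 0 h, 50.7 and 57.9 at 24 h). Neural crest and developmental genes described as CHD7-dependent had 1 measured member, Reln on chromosome 5 (1.90 and 4.95 FPKM at 0 h), and genes of the mitochondrial genome were not analysed here.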

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

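The test in this part was chosen after the result was seen. Lars2, a mitochondrial leucyl-tRNA synthetase gene whose row was fixed beforehand in the list of abundant RNAs taken as a sign of RNA quality and depletion, responded to estradiol in opposite directions, with a log2 ratio of -1.50 in wild type and 1.59 in the knockout, a difference of 3.09. Rps27 did likewise, with -1.46 in wild type, 2.10 in the knockout and a difference of 3.56. Each direction rests on 1 library per group and the differences were not tested.

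Rps27 belongs to a wider pattern in which single copies of multi-copy genes had extreme values, such as Hist1h4n at 1942 FPKM in wild type at 24 h and near 0 in the other libraries. A candidate explanation is that reads were divided unevenly between similar copies, but the sum over copies could not decide it. In the wild-type estradiol response the log2 ratio of the sum was -0.21 for Amd1, 0.09 for Hist1h2ap and 0.504 for Hist1h4n. For Rps27 it was -0.26, taken for knockout against wild type at 0 h. The single copy alone could move the sum in these comparisons by no more than -0.22 (Amd1), whatever the cause. In those comparisons the other copies did not change in the opposite direction by a like amount. Amd2 stood at 89.7 and 90.02 FPKM while Amd1 went from 14.9 to 0.02. In the wild-type estradiol response the sum of Rps27 and Rps27rt went from 2802 to 2769 FPKM (log2 ratio -0.02). Rps27rt thus rose there while Rps27 fell. In the knockout the sum went from 2345 to 2454 FPKM (0.07) and both copies rose. No biological explanation was tested for this pattern, which stays open.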

How the results depend on the processing

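Planned settings and those added after the data were seen (chromosome 5 left out, counting interval, share of genes with the larger response) are given together. Counts were held the same within 1.5-fold, correlations and the slope within 0.1, the shares of genes with the larger response within 10 points and single genes within a log2 of 0.58. Of 213 alternative values for the counts, numbers of lists, correlations, slope, these shares and the Chd7 row, 176 were the same and 37 moved. Those of the Chd7 row, listed at 0, could only be the same. Of 600 for lists standing apart 569 kept the call, 30 lost it and 1 turned, of 880 for the other lists 23 gained a call, and of 14990 for named genes 13891 were the same and 1097 moved, 923 of these with TPM scaling. Leaving out other genes cannot change the ratio of a single gene. Named-gene values with no filter (1715), at a mean of at least 5 FPKM (1425) and without small and predicted loci (1710) were therefore fixed. So were those without chromosome 5 (1565). Median-centring cannot change a list's relative median, its percentile or a correlation, so its 150 list values were fixed too. Median-centred and upper-quartile scaling, no filter, the counting interval and leaving out chromosome 5 moved no count, correlation, slope or share of larger responses beyond these limits, although both scalings moved the split into higher and lower genes, and the numbers of lists standing apart stayed within them in every setting. For the difference of responses, the counting interval kept 36 of the 54 higher genes, which is at the 1.5-fold limit, and 51 of the 56 lower ones. Genes without a transcript length, such as Fam132b (difference 1.02), were kept unchecked. The counts kept by this interval are therefore upper limits, and that of 36 could lie beyond the 1.5-fold limit. No test of differences paired by time or by genotype was run. Where no reason is given, the cause was not tested.

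Counts are given in the order wild-type response, knockout response, knockout against wild type at 0 h, at 24 h, and difference of responses. With a pseudocount of 5 FPKM, by construction smaller ratios, the higher genes numbered 95, 180, 25, 25 and 19 and the lower genes 32, 123, 23, 40 and 33. A pseudocount of 0.1 FPKM gave 180 and 507 lower genes for the responses, 61 higher and 112 lower at 0 h, 118 and 199 at 24 h, and 113 and 111 for the difference. Genes with a mean of at least 5 FPKM, a smaller set, gave 63 lower for the wild-type response, 34 lower at 0 h, 35 higher at 24 h and 28 higher for the difference.

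TPM scaling shifted the all-gene medians to 0.11, 0.83, -0.78, -0.04 and 0.72. It gave 269 higher and 49 lower genes for the wild-type response, 3043 and 39 for the knockout response, 1111 lower at 0 h, and 1327 and 25 for the difference, with a slope of 1.11 and shares of 97.8% and 54.1%. The sum of the knockout at 0 h is 33.9% Snord49a, so this scaling lowers that library's other values by construction. Without small and predicted loci, 15 genes were higher at 0 h and 29 lower in the difference, and the correlations were 0.82 for the responses, 0.52 for the knockout effects and 0.28 for the orthogonal contrasts.

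Of 1715 values of named genes, 503 changed direction with TPM scaling, 125 with upper-quartile scaling and 113 with median-centred libraries. Among those at least 2-fold as deposited, only Myc (0.005) and Wdr12 (0.064) did, in the knockout response with TPM scaling, from that shift. Of 600 values of lists standing apart 49 moved by over 1.5 times, 20 of them with no filter. Histones at 24 h, relative median -0.0017, stood at percentile 48.6 among unmatched lists instead of 99.3. Depth limits low genes, with a counting half-width of 0.74 in log2 at 1 FPKM when nothing is added to FPKM.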

Other observations

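All tests in this part, of library scaling, of Gata1 and of chromosome 5, were chosen after the results were seen. The test of library scaling replaced, after its value was seen, another that took the lowest share over the scalings and left the question open at 54.1% (exact 95% interval 36.9% to 70.5%, lower genes with TPM scaling). The interferon-stimulated list did not stand apart between genotypes (relative medians -0.18 and -0.24 at 0 and 24 h), with 1 of 6 members at least 2-fold lower in the knockout. That member, Psmb9, an immunoproteasome subunit, stood at 1.61 and 2.25 FPKM in wild type and 0.20 and 0.38 in the knockout at 0 and 24 h. Outside the list, Ifi27 stood at 123 and 136 against 39.5 and 50.9, and Ifitm2 at 62.1 and 51.3 against 24.8 and 12.1. Among chromatin genes, Chd3 was at 11.6 and 6.90 FPKM in wild type and 9.16 and 4.56 in the knockout, and Chd2 at 10.7 and 11.2 against 10.4 and 12.0.

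The larger estradiol response of the knockout line is a hypothesis from 1 culture per group. Over 101 shifts of the knockout response, the larger of the shares (higher or lower genes) never went below 88.48% in the replacing test. Like that of the replaced test, its exact 95% interval of 83.8% to 92.2% treats genes as independent, which they are not. A shift that lowers the share of higher genes tends to raise that of lower genes, and the reverse. With both shares high as deposited, the outcome was therefore fixed before this test, which adds no evidence of its own. The shares show only that a single shift of the knockout response does not account for both directions. The slope without chromosome 5 was 1.302, but a dose shift present at both times cancels in the response, so this value cannot decide on extra chromosome 5 dose, whose effects on genes elsewhere stay open. A higher level of active GATA1 in the knockout line was not measured and stays open. Gata1 FPKM as deposited was 1.501-fold that of wild type at 0 h and 1.671-fold at 24 h. This is RNA, and how much of it comes from the introduced fusion is not known. An effect of this higher value cannot be told apart from the knockout, because the line carries both. Ratios of all genes spread more widely in the knockout response (typical deviation from the median 0.41 in log2) than in the wild-type response (0.30). A wider spread from any source, library quality included, raises both shares and the slope, and its source was not tested. Loss of CHD7, clonal differences and a larger share of unresponsive cells in the wild-type culture all stay open and were not tested.

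Chromosome 5 genes were higher in the knockout line as a block. A few strongly changed genes do not account for it, since the 25th percentile of their ratios was shifted by 0.469, and neither does noise at a single time, since the smaller shift of the times was 0.450. An extra copy of the whole chromosome is a candidate explanation, as each of the 6 parts of 20 Mb with at least 20 genes was shifted by at least 0.412, where 3 copies over 2 give 0.58 and 4 over 3 give 0.41. A lost copy in the wild-type line could give a shift of the same sign, and whether either arose from cloning or from loss of CHD7 was not tested.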
